A study of Rattus norvegicus with 3 samples.

How the data were processed

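Per the labels, total RNA was extracted from livers of male SHR and WKY rats of 1 and 3 months, 10 µg were copied into cDNA with the dyes Alexa555 or Alexa647, and the WKY RNA was pooled. The number of animals behind each RNA is not given in the sources used here. Each of the 3 arrays carried 12288 spots in 32 subgrids, of which 894 were empty or unnamed, and 5697 probes on 2 spots each.

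The deposited files hold, for each spot and both channels, the mean raw intensity, the mean and SD of the local background intensity, and a net intensity. The net intensity of the first channel was the raw value minus background for 99.3% to 100% of spots, while the authors had scaled that of the second channel to the first by a factor that varied with intensity. The deposited ratio column is the ratio of the net intensity of the first channel over the second after that scaling. A separate table holds the authors' log2 values, whose scale, centring and direction are not stated in the sources used here. Set against the scanner values spot by spot, they matched log2 of the second channel over the first, with a median absolute difference of 0.00196, 0.00383 and 0.00442. The 95th percentile of that difference was 0.535, 0.555 and 0.630 and the correlation 0.604, 0.565 and 0.688, because some spots differed by several log2 units. The medians of the authors' log2 values were 0.0028, 0.0225 and 0.0202. The software that quantified the spots is not given in the sources used here.

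Ratios were recomputed from the raw intensities. Background was corrected with the normexp model of limma 3.58.1 in R 4.3.3 with an offset of 50, and log2 ratios of the second over the first channel were normalized within each array by global loess with a span of 0.3. Median log2 ratios before normalization were -0.57, -0.65 and -0.73, so loess moved every array by more than 0.1 and all values are relative to the median gene. Spots were kept where the foreground exceeded the local background by 2 SD in at least 1 channel. Of 11394 gene spots, 11286, 11135 and 11267 were present in both channels. Spots of a probe were averaged, and a gene with several probes was represented by the brightest, which concerned 37 genes with 2 probes. Probe names were updated with a table of RefSeq symbols, by accession for 2729 probes, by current symbol for 1051 and by synonym for 521. Another 156 kept the symbol of the file and 1240 had none. Other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and matplotlib 3.10.9 drew the plots.

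Positive values mean higher in SHR on both strain arrays. For the SHR age array, the file headers name the second column as SHR of 3 months, whereas the labels put Alexa647, which the labels give to SHR on the strain arrays, on SHR of 1 month. The second column was the dimmer on all 3 arrays. On the strain arrays the headers name it as SHR, which the labels put in Alexa647. Which dye it holds on the SHR age array is not given in the sources used here. The direction fixed before the data were examined rested on the dyes. The headers were used instead once the files were seen, so the direction of this array stays open.

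With 1 array per comparison no p-value was computed. Genes at least 2-fold apart were counted, and each group of genes was described by its median log2 ratio and its percentile among 10000 random lists of the same size matched on deciles of intensity. The 42 lists cover liver metabolism, sex-biased and growth-related genes, blood pressure control, defence and stress, cell machinery, and markers of cell types in liver and other organs, and were fixed before the data were examined. Genes to be named were also set by a rule fixed before the data were examined: the 12 highest and 12 lowest per array among genes with a symbol and present in both channels, up to 4 members of each list with the largest ratios per array, the 10 highest and 10 lowest for the change with age, and all members of the lists of angiotensin and kallikrein-kinin genes and of reported SHR alleles. A few genes that the rule takes are not reported. Other list members and genes of the computed WKY ratio were named after their values were seen. The rule also took the 4 highest and 4 lowest genes present in 1 channel only, whose bounds are not reported. A single ratio for WKY of 3 months over 1 month was computed as the 1-month strain ratio minus the 3-month strain ratio plus the SHR age ratio, which holds if the same SHR RNA was used on the arrays that share it.

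The pipeline was tested on simulated data with known changes put into the second channel. Intensities and backgrounds were those of the real arrays, but each spot's ratio was replaced by the running median over spots of like intensity. The noise added was about the size of the SD between spots of a probe (0.056, 0.046 and 0.052, pooled). That is well below the SD of the real ratios over genes (0.23, 0.22 and 0.33). A true 2-fold change came back as a median log2 of 0.89, 0.88 and 0.86 on the 3 arrays, and 2, 2 and 0 of 67 such probes reached 2-fold. A true 4-fold change reached 2-fold in 60 of 66, 59 of 65 and 60 of 66 probes, and 0 of 5491, 5448 and 5493 unchanged probes did. At that noise the 2-fold counts miss most changes near 2-fold. The 0 calls among unchanged probes follow from the small noise, so they give no rate of false calls on the real arrays.

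Alternatives fixed before the data were examined were no background correction, plain subtraction, normexp with offset 0, median centring, loess per subgrid, presence in both channels, no filter, the authors' log2 values, a 1.5-fold threshold, an intensity-dependent z-score of 2 within 200 neighbouring genes, random lists without matching, and the mean over the probes of a gene. One more was chosen after the data were seen. On the 3-month strain array 985 spots (8.02%) had a local background over 2 times the median, against 46 and 0 on the others. The fitted model added 314 and 397 intensity units to the channels of that array, which draws ratios of dim genes toward 0, so the model was also fitted without those spots.

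Explanations of 3 patterns were tested. Of 8 tests first run, 5 were replaced or dropped after their results were seen and 3 were added, which left 6. The values of the replaced tests are given with the others.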

Results

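Liver RNA of male rats from 2 strains was compared on spotted oligonucleotide arrays read in 2 colours. The spontaneously hypertensive rat (SHR) is an inbred strain whose blood pressure climbs as it matures, and the Wistar Kyoto rat (WKY) is its normotensive relative. Per the labels, 1 array set SHR against pooled WKY at 1 month, 1 array did so at 3 months, and 1 array set SHR of 1 month against SHR of 3 months. Each of the 3 groups therefore held 1 array, with no replicate and no dye swap, so that every difference below is a value without a replicate check. Median raw intensity in the first and second channel was 3405 and 2270 on the 1-month strain array, 3460 and 2162 on the 3-month strain array, and 2405 and 1448 on the SHR age array. The median over spots of raw intensity divided by local background was 72.6 and 46.1, 73.7 and 40.7, and 57.2 and 30.5. A ratio was obtained for 5650, 5617 and 5652 genes on the 3 arrays. Each probe was printed on 2 spots, and the SD between both spots of a probe, pooled over probes, was 0.056, 0.046 and 0.052 log2 units. That SD covers the printing and scanning of 1 hybridisation, and says nothing of differences between animals.

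At 1 month the question was which liver genes differ between the strains while SHR are still young. The interferon-induced GTPase Gbp2 had a log2 ratio of SHR over WKY of -1.02, and LOC259245, an alpha-2u globulin of the family of urinary proteins that male rat liver secretes, had -1.23. Cish, a growth hormone and cytokine induced inhibitor of STAT5 signalling, had the highest ratio of any named gene at 0.84. Slc38a4, an amino acid transporter of hepatocytes, stood at 0.73, the kinase Map3k8 at 0.68, Camk2d at 0.63, the DNA repair nuclease Mre11 at 0.61, and the chemokine Cxcl1 at 0.60. Cish, Camk2d, Mre11 and Cxcl1 were near the bright end of the array, with log2 intensities of 14.8, 15.5, 14.6 and 15.5, and with median centring, which keeps the intensity trend, their ratios were 1.46, 1.59, 1.17 and 1.55. In all, 0 genes were at least 2-fold higher and 22 at least 2-fold lower in SHR among 5650 genes, and at 1.5-fold these counts were 11 and 137. Of the 22 lower genes, 19 had a mean log2 intensity under 9, close to the dim end of the array. They included Pdap1 at -1.75, Ptbp3 at -1.55, Casc3 at -1.39, Cyp1a1, a target of the aryl hydrocarbon receptor, at -1.28, Zp2 at -1.26, Resp18 at -1.20, Cacng7 at -1.18 and Serpinb2 at -1.15. Smc1a, a cohesin subunit, had -1.48, but its spots differed with an SD of 1.83, so 1 spot decided that value.

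Among the gene groups at 1 month, genes with higher expression in female than in male rat liver lay low in SHR. Their median log2 ratio was -0.15 over 13 genes, 1 of them above 0, at percentile 1.77 among 10000 random lists matched on intensity. Among random lists without that matching the percentile was 2.80, inside the central 95%. Cyp2c7 had -0.71, Fmo1 -0.51, Cyp2a1 -0.30 and A1bg -0.29. Male-biased liver genes also had a median below 0, at -0.13 and percentile 4.15 over 10 genes, with Scd at -0.53, Cyp2c13 at -0.33 and Cyp2c11 at -0.22. Markers of lymphocytes and NK cells had a median of -0.14 over 15 genes at percentile 2.13, with Klrk1 at -0.84, Klrd1 at -0.25 and Nkg7 at -0.23. That group fell inside the central 95% of random lists in 6 of 11 alternative settings. Of the 42 lists examined, 2 lay below and 0 above the central 95% of random lists, where 2.1 lists would be outside by chance. The percentiles describe a single array and are not p-values.

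**Figure D1:**
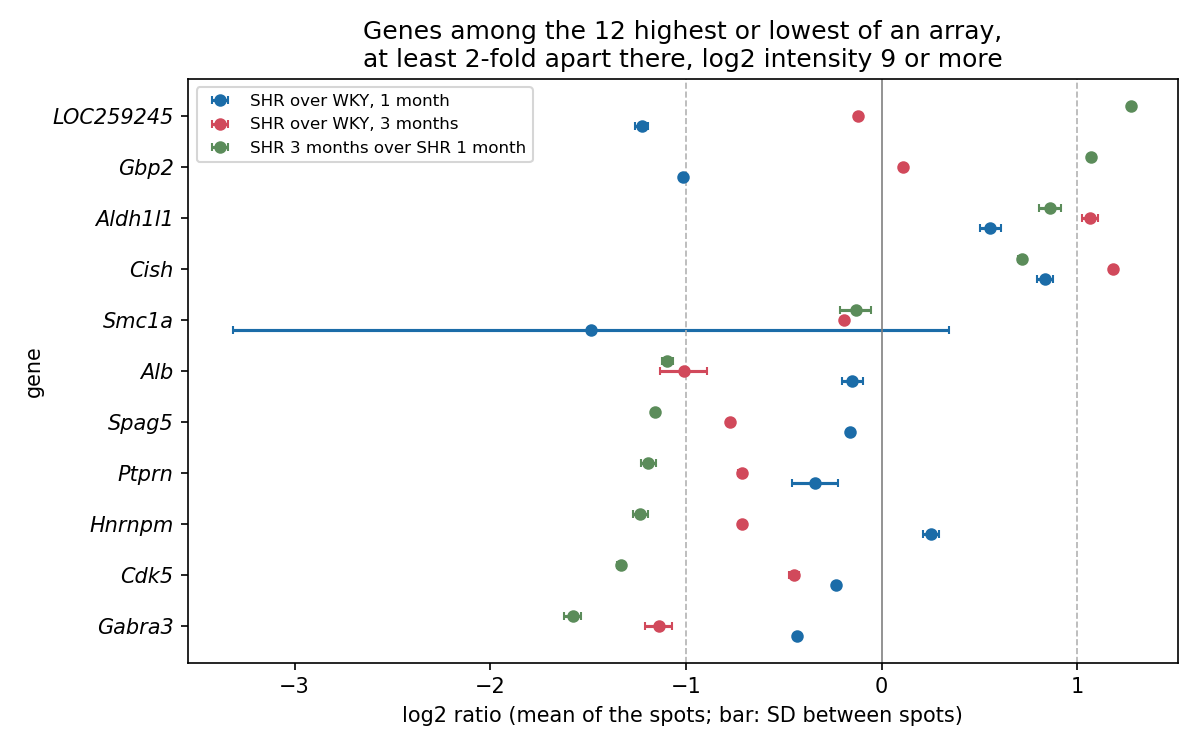
Log2 ratios of genes among the 12 highest or 12 lowest of an array that were at least 2-fold apart on it with a log2 intensity of 9 or more, 1 point per gene and array, with bars for the SD between the 2 spots of the probe. In the headers' direction of the SHR age array, Cish lay above 0 and Gabra3 below 0 on all 3 arrays, while Gbp2 and LOC259245 were at -1.02 and -1.23 on the 1-month strain array and at 1.07 and 1.27 on the SHR age array.

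At 3 months, the age at which SHR hypertension is established, the comparison asked which genes differ between the strains. Cish again had the highest ratio, a log2 value of 1.18, and Aldh1l1, a folate enzyme abundant in hepatocytes, had 1.06. Albumin, the main secreted protein of hepatocytes, stood at -1.01 and Gabra3, a GABA receptor subunit, at -1.14. Prm2 had 0.93, Camk2d 0.92, Mre11 0.81 and Cxcl1 0.67. Cish, Aldh1l1, Prm2, Camk2d and Mre11 were near the bright end of the array, with log2 intensities of 14.4, 15.1, 15.3, 15.3 and 14.3. Over the alternatives their ratios ran from 1.18 to 1.46, 0.88 to 1.70, 0.85 to 1.67, 0.86 to 1.65 and 0.74 to 1.07. At the low end, Septin9 had -0.96, the mitochondrial pyruvate carrier subunit Mpc1 -0.95, the amino acid transporter Slc7a8 -0.88, the transcriptional regulator Cited2 -0.85, Ucp1 -0.85, the cytokine Il6 -0.82 and Jak2 -0.71. At least 2-fold, 2 genes were higher and 4 lower in SHR among 5617 genes, and at 1.5-fold 34 were higher and 84 lower. With the background model fitted without a patch of bright local background, an alternative chosen after the data were seen, the number at least 2-fold lower was 20, and it took in the dim genes Pdap1, Casc3, Zp2 and Timp2.

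Hepatocyte markers lay low at 3 months, with a median of -0.15 over 15 genes at percentile 1.73. Besides albumin, transferrin (Tf) had -0.29 and fetuin (Ahsg) -0.27, and 6 of the 15 were above 0. This group was inside the central 95% in 4 of 11 alternatives, loess per subgrid among them, where its median was -0.033. Markers of stellate cells and matrix had a median of -0.13 over 32 genes at percentile 0.26, with Reln at -0.49, Des at -0.41, Col1a1 at -0.36 and Mmp14 at -0.34. Rgs5, a pericyte gene of the same list, had 0.40, and with median centring the percentile was 12.7. These 2 of 42 lists lay below the central 95% and 0 above, where 2.1 lists would be outside by chance.

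Genes of blood pressure control showed small strain ratios at both ages. The 19 measured genes of the angiotensin and kallikrein-kinin systems had a median of -0.06 at 1 month and -0.03 at 3 months, at percentiles 12.4 and 37.2, and 0 were 2-fold apart. Angiotensinogen (Agt), made mainly by the liver, had -0.17 and -0.03, plasma kallikrein (Klkb1) -0.19 and -0.25, angiotensin-converting enzyme (Ace) 0.10 and -0.36, and the mineralocorticoid receptor (Nr3c2) 0.31 and 0.32. Among 38 vasoactive and nitric oxide genes, 0 were 2-fold apart at either age, and adrenomedullin (Adm) had 0.12 and 0.49. The 6 measured genes with reported SHR alleles were all less than 1.5-fold apart at both ages. The fatty acid transporter Cd36, for which a defective allele has been reported in some SHR colonies, had 0.10 and -0.11. Folr1 had -0.33 and -0.21, Gstm1 -0.14 and -0.10, and Ephx2 -0.01 and 0.07.

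The SHR age array asked how the SHR liver differs between 3 months and 1 month. The file headers name its second column as SHR of 3 months, while the labels put Alexa647 on SHR of 1 month. These conflict only if the second column holds Alexa647, which is not given in the sources used here. The direction used here, 3 months over 1 month from the headers, is therefore not settled. Every sign in this comparison would turn if the second column holds SHR of 1 month. With that direction, LOC259245 had 1.27 and Gbp2 1.07, and both were among the 3 genes at least 2-fold higher at 3 months. Scnn1b, the beta subunit of the epithelial sodium channel, had 0.98, Cxcl1 0.93, Aldh1l1 0.86 and Cish 0.72. Albumin stood at -1.10, transferrin at -0.99, Mpc1 at -1.13, Cited2 at -1.15, Spag5 at -1.16, Ptprn at -1.19, Hnrnpm at -1.23, Cdk5 at -1.33 and Gabra3 at -1.58. In all, 3 genes were at least 2-fold higher and 52 at least 2-fold lower among 5652, and at 1.5-fold 117 and 305. Of the 52 lower genes, 20 had a log2 intensity under 9, among them Shank2 at -1.28, Timp2 at -1.24, Ptpn21 at -1.23 and Slc4a7 at -1.18. Over the alternatives Hnrnpm ran from -1.25 to -0.45 and Shank2 from -2.56 to -0.48, at least 2-fold lower in 8 of 9 and 7 of 8. With the sign turned, the 2-fold counts would be 52 higher and 3 lower at 3 months.

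By group, 6 of 42 lists lay below the central 95% on the SHR age array and 0 above, where 2.1 would be outside by chance. Female-biased liver genes had a median of -0.34 over 13 genes at percentile 0.10, with the prolactin receptor Prlr at -0.78 and Cyp2c7 at -0.76. Sult2a1 had 2 probes with -0.52 and -0.097. Cyp2c12, the best known female-specific cytochrome P450 of rat liver, had 2 probes with -0.03 and -0.88. Male-biased liver genes also had a median below 0, at -0.11 over 10 genes, 3 of them above 0. Their percentile of 15.6 was inside the central 95%. Fatty acid and triglyceride synthesis had a median of -0.25 over 16 genes at percentile 0.54, with Gpam at -0.76, Acacb at -0.59, Fads1 at -0.46 and Scd at -0.38, while Elovl5 had 0.76. Stellate and matrix markers had -0.20 over 32 genes at percentile 0.10, with Des at -0.60, Bgn at -0.59, Mmp14 at -0.54 and Col1a1 at -0.44. The female-biased, fatty acid and stellate groups stayed outside the central 95% in all 11 alternatives, but not all of these could move them. That array had 0 spots of bright background, and lists without matching leave a median as it is. Presence in both channels, no filter and the mean over probes also left these medians unchanged. Hepatocyte markers had -0.22 over 15 genes at percentile 1.99, with Ahsg at -0.48 beside albumin and transferrin. This group was inside the central 95% in 2 of 11 alternatives, normexp with offset 0, at percentile 2.69, and the mean over probes, with a median of -0.090 at percentile 18.7. Conjugation enzymes had -0.20 over 26 genes at percentile 0.63, with Sult1b1 at -0.58 and Gsta2 at -0.55 against Gstt1 at 0.64, but lay inside the central 95% with loess per subgrid and with the authors' values, at percentiles 11.7 and 9.12. Bile acid synthesis and transport had -0.18 over 20 genes at percentile 2.04, with Akr1d1 at -0.75 and Slco1b2 at -0.43, but 0.27 with median centring. In the angiotensin and kallikrein-kinin group the median was -0.04, with Ace at -0.55 and Klkb1 at -0.40. Among transporters tied to blood pressure, Slc12a1, the kidney sodium, potassium and chloride cotransporter, had -0.91 and the adducin Add3 -0.71.

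**Figure D2:**
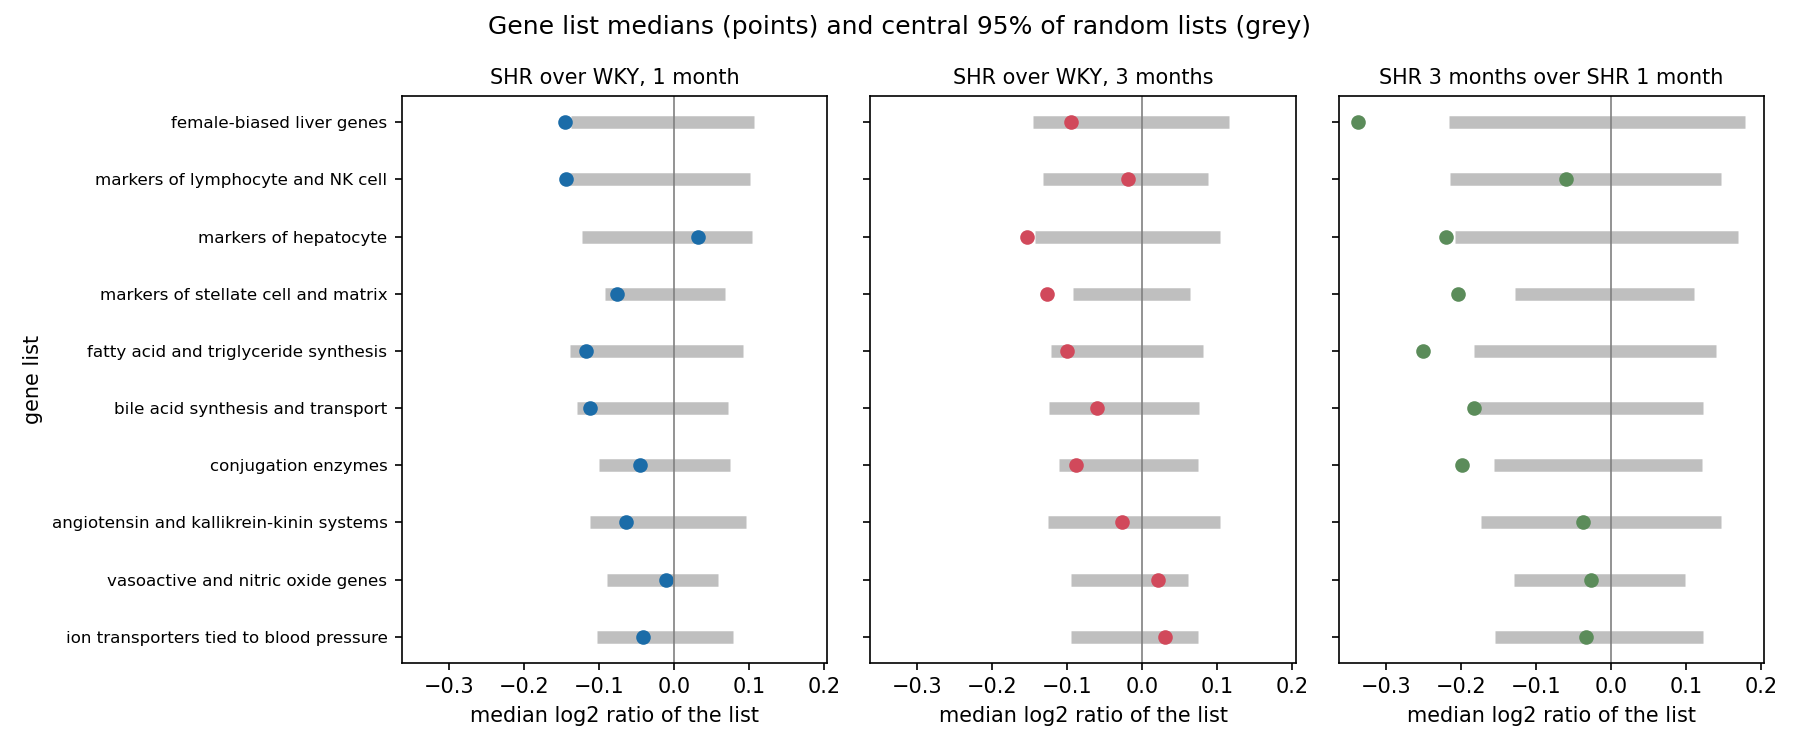
Median log2 ratio of 10 gene lists on each array as points, with grey bars for the central 95% of random lists matched on intensity. They are the 7 lists outside that range on any array and 3 lists of blood pressure control, and female-biased liver genes lay lowest, at -0.34 on the SHR age array in the headers' direction, or highest on that array, at 0.34, with the sign turned.

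The change of the strain ratio with age was taken as the 3-month minus the 1-month log2 ratio, in which dye effects of equal size on both arrays cancel. The ratio of SHR over WKY was higher at 3 months for Gbp2, with a difference of 1.13, and for LOC259245, with 1.11. It was lower for Slc24a2, with -1.01, Anxa2, a calcium-binding membrane protein, with -1.003, Slc7a8 with -0.98, Hnrnpm with -0.97, the methionine sulfoxide reductase Msra with -0.97, Prkcb with -0.90, Il6 with -0.87, albumin with -0.86 and Ucp1 with -0.84. Differences of at least 2-fold were found for 11 genes upward and 3 downward among 5612, and at 1.5-fold for 96 and 63. Several upward genes were dim, among them Pdap1 with 1.37, Casc3 with 1.11, Zp2 and Cyp1a1 with 1.10 each and Serpinb2 with 1.05, and these were under 2-fold without the bright background patch. Smc1a had 1.29, which rests on the spot named above. With that patch left out, 3 genes lay upward and 7 downward, and 6 genes were shared with the 14 of the first count. Markers of lymphocytes and NK cells had a median difference of 0.16 over 14 genes at percentile 99.5, with 11 above 0. Their median strain ratio was -0.14 at 1 month and -0.02 at 3 months. This list was the 1 of 42 outside the central 95% for the difference, where 2.1 lists would be outside by chance. It was inside that range in 4 of 11 alternatives: no background correction, plain subtraction, the authors' values and the model without the bright patch, where its median was 0.048.

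No array set WKY of 3 months against WKY of 1 month, so this ratio was computed by chaining the 3 arrays, which adds their errors and leaves a dye effect in the sum. Female-biased liver genes had a computed median of -0.42 over 13 genes, below all 10000 random lists, fatty acid and triglyceride synthesis -0.32 over 16 genes at percentile 0.17, and iron and heme genes -0.33 over 15 genes at percentile 0.56. With the sign of the SHR age array turned, these medians were 0.15 at percentile 87.5, 0.10 at percentile 87.1 and 0.24 at percentile 98.985, so their direction is as open as that of the array. Anxa2 had a computed ratio of 1.05, or 0.96 with the sign turned, and the glycine transporter gene Slc6a5 had 1.08, or 0.20 turned. The dim genes Pdap1 and Casc3 had -2.53 and -2.32, or -0.22 and 0.10 turned, and -1.81 and -1.49 without the bright patch. At least 2-fold, 12 genes were higher and 121 lower at 3 months among 5610. These counts were 6 and 43 without the bright patch, with 48 genes in common, and 141 and 29 with the sign of the SHR age array turned.

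The log2 ratios of the 3 arrays were correlated across genes, which are not independent replicates. Pearson's r was 0.481 between the strain arrays of both ages (Spearman's rho 0.538), 0.557 between the 1-month strain array and the SHR age array (rho 0.541), and 0.709 between the 3-month strain array and the SHR age array (rho 0.726). The last 2 values would turn negative with the sign of the SHR age array. All 4 genes at least 2-fold lower in SHR at 3 months, albumin and Gabra3 with 2 transcripts without a current symbol, were also at least 2-fold lower on the SHR age array. Both arrays hold SHR of 3 months on the same side of the ratio in the headers' direction, so a shared RNA alone would give such an overlap. Of the 22 genes at least 2-fold lower in SHR at 1 month, 11 were also at least 2-fold lower on the SHR age array and 2, Gbp2 and LOC259245, at least 2-fold higher, while 20 of the 22 had the same sign on all 3 arrays, or 1 with the sign of the SHR age array turned. In the 1-month strain array and the SHR age array the shared RNA, SHR of 1 month, stands on opposite sides of the ratio, so error in that RNA would give a negative correlation and opposite signs for single genes.

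**Figure D3:**
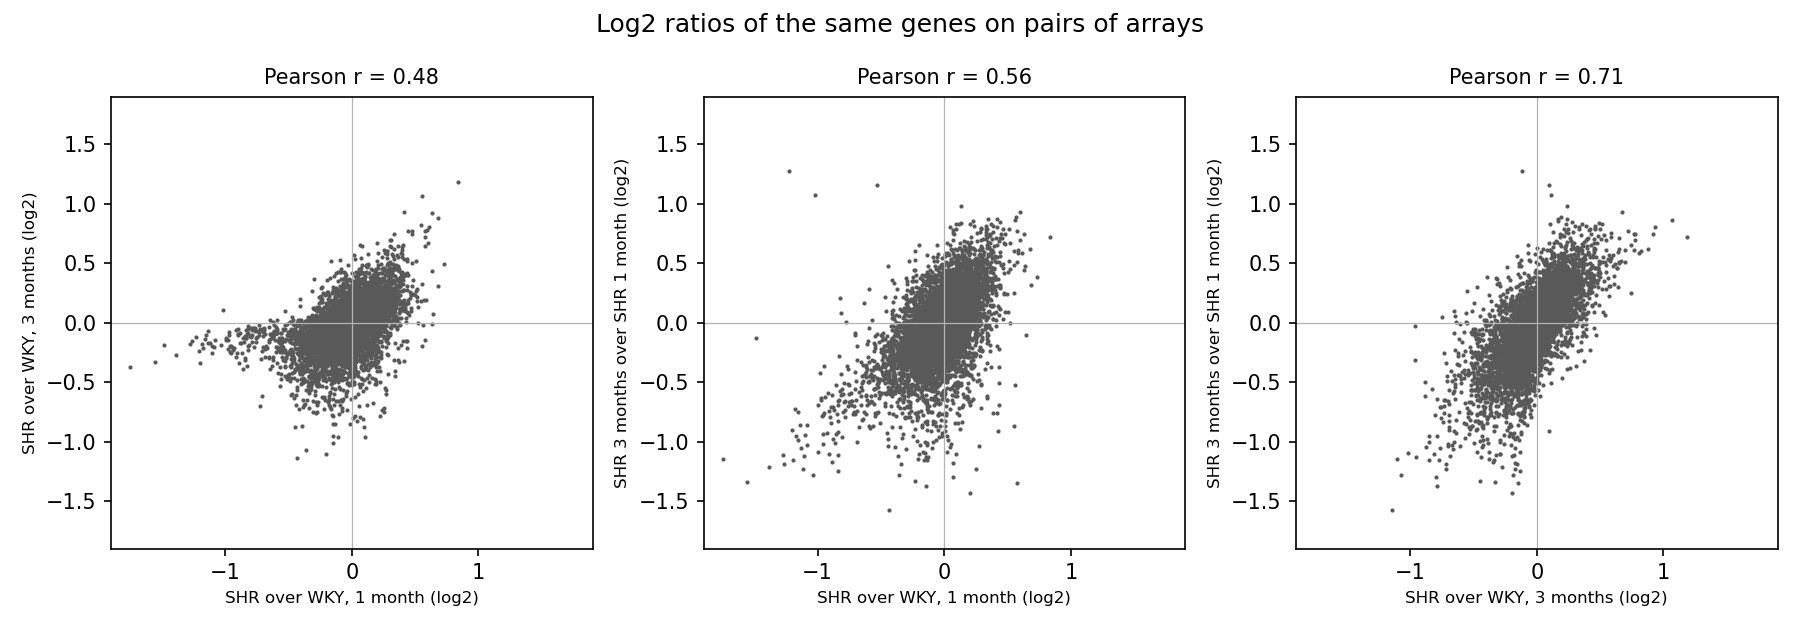
Log2 ratio of each gene on 1 array against another, 1 panel for each pair of the 3 arrays, with 1 point per gene. Pearson's r was 0.481, 0.557 and 0.709.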

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

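The values without bright background were chosen after the result was seen, and no other test was run for the results given here.

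Spots that the files mark as empty gave signal in places. Of 366 such spots outside the last row of the subgrids, 52 were brighter in the first channel than every one of the 512 empty spots of the last row on all 3 arrays. Their median raw intensity was 1729, 1751 and 934, and the brightest reached 33560, 37718 and 25878. What was printed there is not given in the sources used here.

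The genes reported here as highest or lowest on a strain array or in the change with age were looked at. Genes named only as list members were not counted, and some of them, such as Ace, also changed sign. Of the genes looked at, 5 had strain ratios of opposite sign at the 2 ages. Both ratios were further from 0 than 2 times the pooled SD between spots (0.056 at 1 month and 0.046 at 3 months). Slc7a8, Prkcb, Il6 and Ptp4a2 also changed sign, but their 1-month ratios of 0.10, 0.09, 0.04 and 0.01 were within that distance, as was the 3-month ratio of Slc6a5, at -0.01. Each rests on 1 array per age, and the difference was not tested. The SD between spots covers 1 hybridisation, so it does not gauge error between arrays. Genes picked for a large change with age are also more likely to show opposite signs. The 1-month ratios of Anxa2, Slc24a2, Hnrnpm and Msra were about as large as the SD of ratios over genes on that array, 0.23. Gbp2, an interferon-induced GTPase, had -1.02 at 1 month and 0.11 at 3 months, a difference of 1.13, or 1.16 without bright background. Anxa2, a calcium-binding membrane protein, had 0.25 and -0.75, a difference of -1.003, or -1.07 without bright background. Slc24a2, a sodium and calcium exchanger, had 0.23 and -0.79, a difference of -1.01, or -1.05. Hnrnpm, an RNA-binding protein, had 0.25 and -0.72, a difference of -0.97 in both models. Msra, which repairs oxidised methionine, had 0.24 and -0.73, a difference of -0.97 in both. On the SHR age array, Gbp2 stood at 1.07, Hnrnpm at -1.23, Slc24a2 at -0.64, Msra at -0.26 and Anxa2 at 0.05, with the open direction of that array.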

How the results depend on the processing

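All alternatives but normexp without bright background were fixed before the data were examined, and that setting was chosen after. Counts are given as genes at least 2-fold higher and lower, and where only some are given the others stayed within 1.5 times the first count. The order is always the 1-month strain array, the 3-month strain array, the SHR age array, the change with age and the computed WKY ratio. With the settings of the report, higher genes made up 0%, 33.3%, 5.45%, 78.6% and 9.02% of the calls. The SHR age and computed WKY values here rest on the headers' direction of the SHR age array, which is open, and with its sign turned those 2 shares were 94.5% and 82.9%. With the sign turned, a share on the SHR age array becomes its remainder to the whole, and that of computed WKY, counted at 2-fold in 9 alternatives, ran from 44.6% with median centring to 83.6% without a filter. The cause was not tested for any shift below except where stated.

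With plain subtraction of background there were 5 and 71 genes, 12 and 91, 17 and 123, 48 lower for the change with age and 45 higher for computed WKY. Higher genes made up 11.7% at 3 months, 21.3% of the change with age and 28.8% of computed WKY. The correlations were 0.572 between both strain arrays and 0.598 between the 1-month strain array and the SHR age array. The median was -0.18 for stellate and matrix markers at 3 months and 0.050 for the change of lymphocyte markers. With normexp at offset 0 there were 6 and 77 genes at 1 month, 16 and 120 on the SHR age array, 54 and 6 for the change with age (90.0% higher) and 59 higher for computed WKY (26.2%). The correlations were 0.436, 0.619 and 0.637. The offset draws ratios of dim genes toward 0 by construction. Without background correction 40 genes were lower at 3 months (4.76% of calls higher), 5 and 12 differed with age (29.4%) and 45 were lower for computed WKY. The correlations were 0.615 between both strain arrays and 0.757 between the 3-month strain array and the SHR age array. The medians were -0.17 for stellate and matrix markers at 3 months and 0.036 for the change of lymphocyte markers. With normexp without bright background 20 genes were lower at 3 months (9.09% of calls higher), 3 and 7 differed with age (30.0%), and 6 and 43 were counted for computed WKY. The same correlations were 0.618 and 0.774, and the change of lymphocyte markers was 0.048.

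With median centring, which leaves the intensity trend in the ratios, there were 152 and 65 genes (70.0% higher), 106 higher at 3 months (97.2%), 215 higher on the SHR age array (75.7%), 91 and 18 for the change with age, and 350 and 471 for computed WKY (42.6%). The correlations were 0.622, 0.833 and 0.754. At 1 month the medians were -0.21 for female-biased genes and -0.32 for lymphocyte markers, and at 3 months -0.23 for hepatocyte markers. On the SHR age array they were -0.34 for fatty acid synthesis, -0.29 for conjugation enzymes, and -0.32 for both hepatocyte and stellate markers. The bile acid list reversed there, from -0.18 to 0.27. With loess per subgrid 5 genes were higher at 1 month (18.5%) and 1 higher and 1 lower at 3 months (50%). The correlations were 0.466, 0.540 and 0.729, and the medians -0.081 for lymphocyte markers at 1 month, -0.033 for hepatocyte markers at 3 months, and -0.091 for conjugation enzymes and -0.19 for female-biased genes on the SHR age array.

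With the authors' values there were 44 and 74 genes (37.3% higher), 49 and 74, 56 and 129 (30.3%), 34 and 40 (45.9%), and 68 higher for computed WKY (34.9%). The correlations were 0.537, 0.592 and 0.668, and the medians -0.040 for lymphocyte markers at 1 month, -0.17 for stellate markers at 3 months and -0.099 for conjugation enzymes on the SHR age array. The z-score of 2 gave 97 and 147 genes (39.8%), 85 and 167, 95 and 165 (36.5%), 99 and 170 (36.8%), and 110 higher for computed WKY (46.2%). At 1.5-fold there were 11 and 137, 34 and 84, 117 and 305 (27.7%), 96 and 63 (60.4%), and 152 and 363 (29.5%), since a lower threshold takes in more genes. Without a filter 10 genes were lower at 3 months (16.7%) and 9 for the change with age (52.6%), and the correlations were 0.468 and 0.691 between the strain arrays and between the 3-month strain array and the SHR age array. The mean over probes put hepatocyte markers on the SHR age array at -0.090.

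Over all settings, 45 of the alternative counts stayed within 1.5 times the first count and 65 did not, 100 list medians stayed close, 20 moved and 1 reversed, and 7 correlations stayed close and 20 moved. For the 12 highest and 12 lowest genes of each array 433 values stayed within the spread between spots and 208 moved, and 0 changed sign. The median foreground was not run, since the files read give means only. No array could be left out, with 1 array in each group. No paired analysis was possible because each group held 1 array and the shared replicate number 1 does not link animals. The median over spots of raw intensity divided by local background ran from 30.5 to 73.7 over arrays and channels.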

Other observations

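The test of the intensity trend and that of the direction of the SHR age array were chosen before the results they measure were seen, and the other 4 were chosen after, as were the values after median centring and the slopes with the sign turned.

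Iron and heme genes had a median of -0.20 over 16 genes on the SHR age array, in the direction from the file headers, at percentile 3.53 and thus inside the central 95% of random lists. Of these genes 5 were at least 1.5-fold lower, including transferrin (Tf) at -0.99, Ireb2 at -0.88, Fth1 at -0.67 and the erythroid enzyme Alas2 at -0.61. Hmox1, which degrades heme, had 0.37. In the growth hormone and IGF axis the medians were near 0, at 0.00, 0.02 and -0.03 over 20 genes, although Cish was at 0.84, 1.18 and 0.72 on the 3 arrays. Igf1 had -0.21, -0.17 and -0.54, Stat5a 0.30, 0.22 and 0.36, Jak2 -0.18, -0.71 and -0.45, and Socs2 0.11, 0.04 and 0.16. Over all 42 lists, medians ran from -0.15 to 0.11 at 1 month, from -0.15 to 0.10 at 3 months and from -0.34 to 0.096 on the SHR age array, so the lists of defence, stress, cell machinery and other organs not named here lay within the range of random lists.

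The ratios of the 3 arrays moved together across genes, also where shared RNA would set them against each other. An intensity trend left by the normalization is argued against as the whole cause: with each ratio taken relative to its 200 neighbours in intensity the lowest of the 3 correlations was 0.485 (0.481 before), and on median-centred ratios, which keep the trend, the same step lowered that correlation from 0.622 to 0.486. SHR moving further from an unchanging WKY with age was the biological explanation tested. Without error it would give a slope near 1 of the 3-month strain ratio on the sum of the other ratios. The slope was 0.452 without bright background (0.313 with it), or -0.398 and -0.350 with the sign of the SHR age array turned. Neither direction gave a slope near 1, but the slope cannot decide. Error in a sum of 2 single arrays draws it toward 0, and a channel effect carried by all arrays shifts it as well. A difference between channels particular to each probe may account for the pattern, but its test cannot decide. Over 37 genes with 2 probes, the mean ratio of 1 probe and that of the other correlated at 0.119 (95% bootstrap interval -0.179 to 0.432). That was below the lowest correlation between arrays, a bound chosen after the values were seen. The change of the strain ratio with age, in which an equal channel effect cancels, correlated as weakly between probes, at 0.0944. Poor agreement between probes of a gene for any other reason would thus give the same value. True strain and age differences remain open, since no dye swap was made.

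Probes for liver transcripts were about as bright as probes for transcripts of other organs. Hepatocyte markers had a median log2 intensity of 11.6 (percentile 60.6 among random lists) and markers of brain and testis 11.3 (percentile 53.0), against 11.3 over all genes. Differences in efficiency between probes may hide the order of transcripts, since the brightness of 2 probes of a gene correlated at 0.0928 (-0.221 to 0.380). Whether the ratios follow the named transcript stays open, because the change of the strain ratio with age correlated at 0.0944 between probes (-0.216 to 0.409), an interval too wide to decide. No biological explanation was tested for this pattern.

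The direction of the SHR age array was tested with a pair of values in which an equal dye effect cancels. The change of the strain ratio with age and the SHR age ratio relative to the mean strain ratio correlated at 0.221 with the settings of the report and at 0.327 without bright background, a setting chosen after the data were seen, where the bound set beforehand for correct headers was 0.1. That test decides nothing, since a dye effect of free size on each array, fitted to the 3 correlations, gives the observed r by construction and cannot be excluded by it, and the value ran from -0.176 to 0.327 over the alternatives, the highest being the one without bright background. Of the 10 genes at least 2-fold different between ages without bright background, 7 had the same sign in both measures. Gbp2 and LOC259245 were low in SHR at 1 month and near WKY at 3 months, which is in line with the headers' direction but was read from genes picked for that course, so the direction stays open.

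Of 8 tests first run, 5 were replaced or dropped after their results were seen, 3 were kept and 3 added. Among those set aside, the 1-month strain ratio and the SHR age ratio had been predicted to correlate below 0 if shared RNA drove the correlations, and r was 0.557. The lowest correlation with loess per subgrid had been predicted above 0.1 under a dye effect particular to probes and was 0.466. The number of genes 2-fold apart at 3 months without bright spots had been predicted at 1.5 times the first count or more and was 22. The SD of ratios on the 3-month strain array had been predicted below that at 1 month with plain subtraction, and the difference was 0.0768. The percentile of hepatocyte markers in brightness had been predicted inside the central 95% of random lists and was 60.6.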
